A study of Mus musculus with 6 samples.

How the data were processed

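Gene expression in epididymal white adipose tissue, the visceral fat pad beside the male reproductive tract, was measured with 1-colour bead arrays in male C57BL/6J mice. Per the labels' protocols, the mice arrived at 4 weeks of age and were fed a low-fat diet (LFD, 10% of calories from fat) or a high-fat diet (HFD, 45% of calories from fat) for 16 weeks, 9 mice per diet and 18 in all, and were 21 weeks old at sampling. There are 3 arrays per diet. The sources used here do not say whether an array holds RNA of 1 mouse or of a pool, so p-values measure only the spread between these arrays. Total RNA was extracted with TRIZOL, checked on a Bioanalyser, and 550 ng was amplified to biotin-labelled cRNA, per the labels' protocols.

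The authors deposited a scanner table with a linear bead signal intensity and a detection p-value for 45281 probes on each of the 6 arrays. The submitters' processing notes name GenomeStudio 2009.2 and R 2.4.1, without giving their roles. The deposited intensity has no background subtracted: probes with a detection p near 0.5 read 132 to 153 on the 6 arrays, and array means differ. The deposited detection p-value moves in steps of 1 in 936, as a rank among 936 negative controls would. The authors also deposited a processed table of log2 values for 20909 of these probes. All 6 of its columns have the same median of 8.90 and the same set of quantiles, as quantile normalization gives, and within each array its order of probes is that of the scanner signal. The rule by which the authors chose these probes, and any background step, are not given in the sources used here.

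The files identify probes only by the manufacturer's probe identifier. Of the 45281 identifiers, 0 matched the gene table used here, so no probe is named by gene or placed in the genome. The 40 gene lists and the rule for named genes that were fixed before the data were examined could not be applied for this reason: no list was tested and no list score was computed. The planned choice of 1 probe per gene was also not possible, and every probe that passed the filter was tested as its own feature. Tissue composition could not be examined with marker genes either.

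From the intensities, background was corrected with normexp and values were quantile normalized with neqc of limma 3.58.1 in R 4.3.3. The background parameters were estimated from the detection p-values because the files hold no control probes, and an offset of 16 was added before log2. A probe was tested if its detection p was under 0.05 on at least 3 of the 6 arrays, which kept 21317 probes (47.1%) and left out 23964. HFD was compared with LFD by lmFit and eBayes of limma, with no covariate and with Benjamini-Hochberg adjustment over the tested probes at a threshold of 0.05. A second count required at least a 2-fold change. With 3 arrays against 3, a 2-sided exact permutation test of a single value cannot give a p below 0.1. The number of arrays limits the precision of every value.

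Of the probes past the threshold whose 3 values in one diet all lay above those in the other, the 2 with the largest rise and the 2 with the largest fall are named. The rule fixed beforehand took 8 of each. It was shortened because the identifiers carry no gene, and ranked only probes detected on at least 1 array of each diet, since a level below background has no order. For a probe detected on no array of a diet, the fold is a lower bound. It sets the mean of the brighter diet against the dimmer diet's mean of, per array, the higher of the lowest normalized signal of any detected probe and the probe's own value.

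The fit was tested on simulated arrays that carried the real brightness of each array and probe levels taken from the data. Their background was drawn from a normal distribution with each array's own centre and spread, in part shared by a probe across arrays. A probe's level was its mean signal above background over the 6 arrays, scaled for brightness and set to 0 where negative. Noise of undetected probes was thereby carried as signal. At the real brightness, more simulated probes passed the filter than the 21317 in the data. The scatter between arrays was 1 value for all probes, the median SD of those with detection p under 0.01 on all 6 arrays. The 200 changed probes, among 24069 tested, were drawn only from these bright probes, so changes in dimmer probes were not simulated. Of 100 probes changed by 1 on the log2 scale, 89 were called in the right direction, and of 100 changed by 2, all 100 were called. Of 23869 unchanged probes 537 (2.25%) were called, against 189 of all 200 changed ones. Most calls in this simulation, where only 200 probes changed, were therefore false. With this difference in brightness and these simulated levels, the false share of calls exceeded the threshold of the adjustment. That share depends on both settings and does not carry over to the data. With equal brightness, 10 of 20994 unchanged probes were called and 191 of 200 changed ones. In a simulation at the real brightness with no changed probe, 383 of 24565 probes were called, 0 of them among the 14739 probes of the 6 brighter deciles.

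Alternatives fixed before the data were examined were no background correction, the authors' processed values, median scaling, cyclic loess, no filter and a stricter filter on dim probes, a trended robust variance, array weights, the replicate number as a block, and leaving out each array. A slide block was not run because the files name no slide. Nothing in the labels ties samples with the same replicate number in the 2 diets. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.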

Results

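Transcript levels in epididymal fat were compared between mice fed for 16 weeks on a diet with 45% of calories from fat and mice fed a diet with 10%, to find which transcripts differ in fat tissue after a long high-fat diet. Both diets were represented by 3 arrays with 45281 probes each. The values are bead signals, which were background corrected, quantile normalized and analysed on the log2 scale with limma. Probes carry no gene names in the files, so results are given for groups of probes and for 4 probes by identifier.

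The arrays of the high-fat group were brighter than those of the low-fat group before any normalization. Mean signal was 1162 ± 87.7 (SD, n = 3) in the high-fat group and 608 ± 28.0 (SD, n = 3) in the low-fat group, a ratio of 1.91. Each high-fat array exceeded each low-fat array, and the exact 2-sided permutation p of 0.1 is the smallest that 3 against 3 arrays can give. The background differed less. Signal at a detection p of 0.5 was 147 ± 4.89 (SD, n = 3) against 138 ± 5.90 (SD, n = 3), a ratio of 1.07 (exact 2-sided permutation p = 0.2). Over the 15160 probes with detection p under 0.01 on all 6 arrays, the signal above background was 2.32 times as high in the high-fat group. The highest single signal differed less, by a ratio of 1.23. In the high-fat group 21580 to 21757 probes were detected per array at p under 0.05, and in the low-fat group 18947 to 19673. The files name no slide or scan batch, so whether a batch coincided with diet was not tested.

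**Figure D1:**
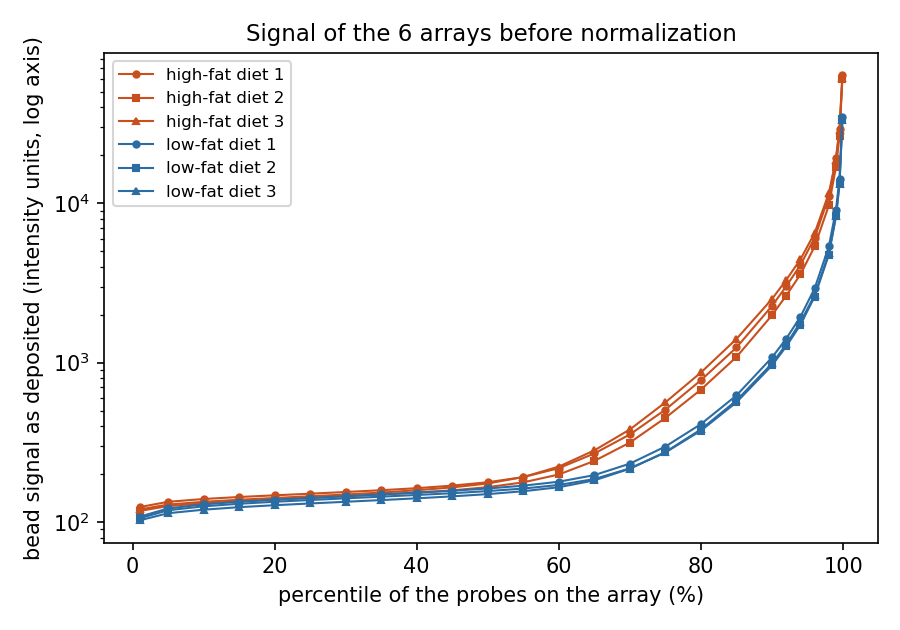
Bead signal as deposited (log axis) at percentiles of the 45281 probes of each array, with 1 line per array, low-fat in blue and high-fat in orange. The lines run close together among the dim probes and part above the median, where the 90th percentile was 961 to 1078 on the low-fat arrays and 1984 to 2509 on the high-fat arrays.

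After normalization the arrays separated by diet. Across the 21317 tested probes, Pearson's r between arrays was 0.982 to 0.989 within the low-fat group, 0.993 to 0.995 within the high-fat group and 0.923 to 0.944 between diets. These are correlations across probes, which are not independent replicates. No pair of arrays had more than 2 identical signals, so no array was a copy of another. The first principal component held 80.7% of the variance. The low-fat arrays lay at -63.4 to -52.3 on it and the high-fat arrays at 54.8 to 65.3. The second component held 8.87% of the variance and set low-fat array 2, at -39.4, apart from low-fat arrays 1 and 3, at 14.0 and 22.1.

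Of the 21317 tested probes, 10660 (50.0%) differed between diets at an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment. In the high-fat group 5305 probes rose and 5355 fell. The median absolute change of the called probes was 1.67-fold, and 69.2% of them changed by less than 2-fold. The median standard error of a log2 fold change was 0.13. The 2 diets did not overlap in 13014 tested probes (61.0%), where chance gives 10% for 3 against 3 arrays, and 10576 of the called probes were among them. The split into rises and falls changed with the scaling. Rises made up 49.8% of calls under quantile normalization, 94.4% when arrays were scaled to the median of all probes, and 33.1% when they were scaled to the median of the probes detected on all arrays. The median log2 change of all tested probes was -0.01, 0.82 and -0.18 under these scalings, so directions are relative to that median.

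The largest changes were more often rises than falls. By fitted fold, a change of at least 2-fold was seen for 3280 called probes, of which 1948 rose and 1332 fell. This order turned, to 1243 rises and 2521 falls, when arrays were scaled to the probes detected on all of them, and the 2 counts were 862 and 860 for probes with detection p under 0.01 on all 6 arrays. By fitted fold at least 4-fold, 475 rose and 99 fell, at least 8-fold, 150 rose and 15 fell, and at least 16-fold, 43 rose and 2 fell. These counts include probes detected in one diet only, whose fitted fold is not a measured size. Among the 19605 probes detected on at least 1 array of each diet, 1335 rose and 1168 fell by at least 2-fold, 323 rose and 90 fell by at least 4-fold, 98 rose and 15 fell by at least 8-fold, and 28 rose and 2 fell by at least 16-fold. Of the probes detected only in the high-fat group, the lower bound supports at least 4-fold for 66 and at least 8-fold for 23. Rises of at least 4-fold outnumbered falls under every alternative, all added after the data were seen for this count, most narrowly, with 348 rises and 274 falls, under scaling to the probes detected on all arrays. The counts themselves depended on the processing: 158 rises and 19 falls without background correction, 197 and 22 on the authors' deposited log2 values, 215 and 57 for probes with detection p under 0.01 on all 6 arrays, and 1262 and 19 under median scaling over all probes. The count of falls rested in part on low-fat array 2: without it, 187 probes fell and 505 rose by at least 4-fold. The 2-fold count was 1124 without background correction. It was 1331 on the authors' deposited log2 values, which differ in the probes held as well as in processing. By limma's treat test against a 2-fold change, an alternative added after the data were seen, 760 probes rose and 222 fell.

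**Figure D2:**
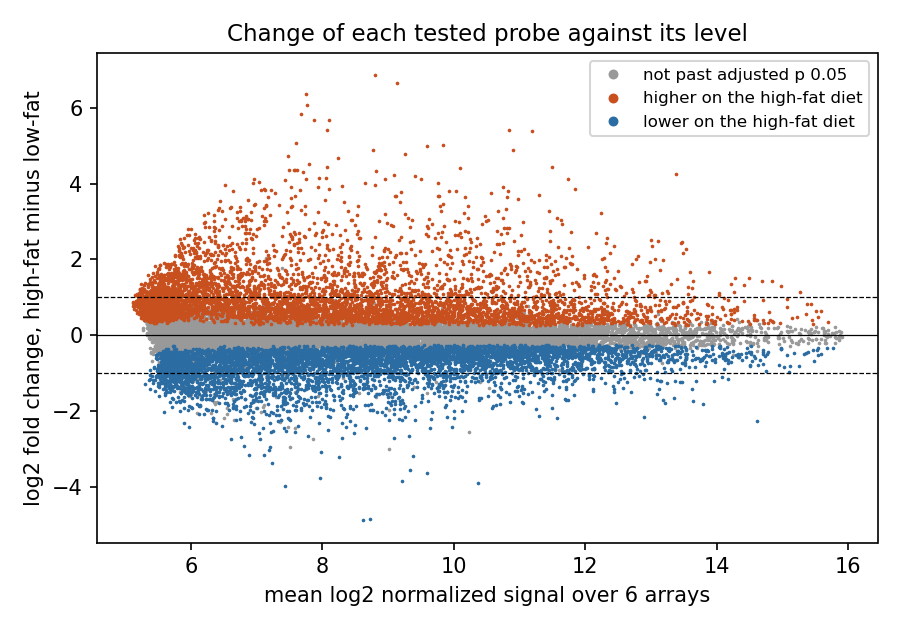
Log2 fold change (high-fat minus low-fat) of each of the 21317 tested probes against its mean log2 normalized signal over the 6 arrays, with dashed lines at 2-fold. Probes past adjusted p 0.05 are orange (5305 higher) or blue (5355 lower). Under quantile normalization rises reach larger folds than falls, and calls occur at every level.

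The share of called probes differed little by level. The tested probes were split into 10 groups of equal size (deciles) by mean level. Among them 47.3% of the brightest decile and 55.6% of the dimmest decile were called. In the brightest decile 20.6% rose and 26.7% fell. In the dimmest decile 42.4% rose and 13.1% fell, and the median log2 change there was 0.34 against -0.05 in the brightest decile. Simulated arrays of the same brightness with no changed probe gave 137 calls among 2457 probes (5.58%) in the dimmest decile, and the detection filter admits the probes detected only on high-fat arrays, 1485 against 227 detected only on low-fat arrays. In the 6 brighter deciles 6311 of 12790 probes were called, 2841 higher and 3470 lower, and those simulated arrays gave 0 calls. With few calls, the adjustment demands a smaller unadjusted p than in the data. The simulation also scaled each array by a single gain with no batch effect on single probes, and carried noise of undetected probes as signal. The simulated shares are therefore not the rate of false calls here.

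The 2 probes with the largest measured rises were ILMN_2625377 and ILMN_2992709. ILMN_2625377 had a log2 level of 5.82 ± 0.48 (SD, n = 3) in the low-fat group and 12.46 ± 0.19 (SD, n = 3) in the high-fat group. Its log2 change was 6.65 with a standard error of 0.24 (limma, adjusted p = 5.15e-06). It was detected on 2 of the 3 low-fat arrays, and its low-fat bead signal of 167 ± 17.1 lay close to the low-fat detection limits, so neither its fold nor its rank is well measured. Without background correction its log2 change was 4.75, below the 4.77 of ILMN_2992709. ILMN_2992709 was detected on all 6 arrays and went from 8.13 ± 0.36 to 13.54 ± 0.10 (SD, n = 3 each). This is a log2 change of 5.40 with a standard error of 0.18, or 42.4-fold (limma, adjusted p = 3.90e-06). In the authors' deposited table the 2 changes were 5.09 and 4.96.

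The 2 largest measured falls were those of ILMN_1244261 and ILMN_3111685, both detected on all 6 arrays. ILMN_1244261 had a log2 level of 11.06 ± 0.69 in the low-fat group and 6.17 ± 0.41 in the high-fat group (SD, n = 3 each), and fell by 4.89 on the log2 scale with a standard error of 0.36 (limma, adjusted p = 6.55e-05). ILMN_3111685 had 11.16 ± 0.75 and 6.30 ± 0.11 (SD, n = 3 each), and fell by 4.86 with a standard error of 0.34 (limma, adjusted p = 5.19e-05). High-fat bead signals of 226 ± 36.9 and 235 ± 19.3 were near the detection limit of 170 to 182. Without background correction the log2 changes of ILMN_1244261 and ILMN_3111685 were -3.29 and -3.36. The low-fat arrays spread in the same order for both. The bead signals of ILMN_1244261 were 1521, 847 and 2163 on low-fat arrays 1, 2 and 3, and those of ILMN_3111685 were 1744, 846 and 2291. In the authors' deposited table the changes were -3.67 and -3.72.

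**Figure D3:**
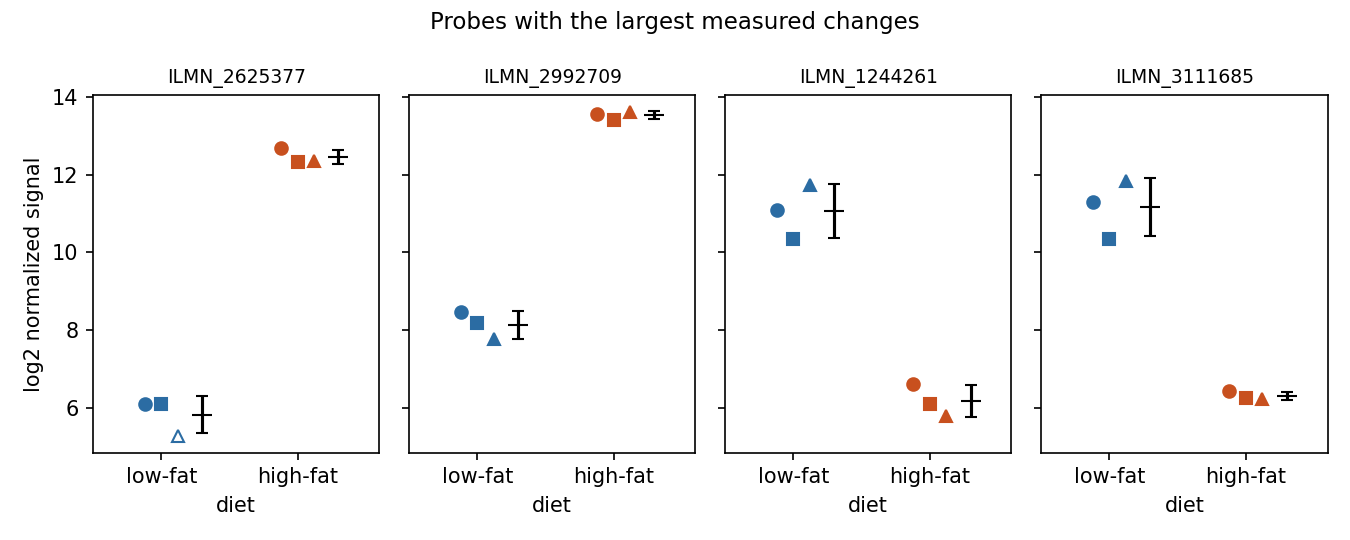
Log2 normalized signal of the 4 named probes on each array, low-fat in blue and high-fat in orange, with the replicate number as circle (1), square (2) or triangle (3) and the bar as mean ± SD of 3 arrays. The open symbol is a value with detection p of 0.05 or more. In each probe the 2 diets do not overlap, and low-fat array 2 is the lowest low-fat value of ILMN_1244261 and ILMN_3111685.

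A set of probes was detected in one diet and not in the other. On every high-fat array and no low-fat array 1485 probes were detected at p under 0.05, and 1291 of them were called as higher. On every low-fat array and no high-fat array 227 were detected, and all 227 were called as lower. For such probes a fold is only a lower bound. Of the called probes detected only in the high-fat group, 214 were at least 2-fold, 66 at least 4-fold and 23 at least 8-fold higher, and the largest bound was at least 88.8-fold. Of those detected only in the low-fat group, 62 were at least 2-fold and 4 at least 4-fold lower in the high-fat group, with a largest bound of at least 5.89-fold. At a detection p under 0.01 the 2 counts were 1384 and 123. Beside these counts stands the brightness of the high-fat arrays, 2.32 times that of the low-fat arrays above background.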

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

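The count of called probes stayed within 1.5 times of 10660 under 15 of 16 alternatives. Median scaling over all probes gave 17501 (16519 rises, 982 falls). By construction this setting aligns background, since only 41.8% to 48.0% of probes were detected per array. Leaving out each array gave 8572 to 10603 calls, and 3036 to 3524 of at least 2-fold. The count of 3280 probes of at least 2-fold became 1124 without background correction, 1331 on the authors' processed values, 8183 under median scaling over all probes, 1722 for probes with detection p under 0.01 on all 6 arrays (15160 tested), and 982 by limma's treat test, which asks for more than a 2-fold estimate. Of the main calls, 9341 were also called, with the same sign, on the authors' values, and 10151 of the 10187 called probes found in both tables had the same sign there. For probes called at least 2-fold here that occur in both tables, the authors' log2 change was a median 0.98 of the one here in the brightest decile and 0.25 in the dimmest, as background left in the signal would give. The rise share of calls moved to 33.1% (3902 rises, 7883 falls) under scaling to the probes detected on all arrays. The 4 named probes kept their direction and adjusted p under 0.05 in limma under every alternative that tested them, with adjusted p from 3.57e-09 to 0.00106. They were picked as the largest measured changes on these same arrays, so the selection favoured this outcome. The ratio of within-diet SD, low-fat over high-fat, was 1.22 and reversed to 0.961 under median scaling over all probes and 0.979 over probes detected on all arrays; the cause was not tested. With the replicate number as a block, 9645 probes were called, 3308 of at least 2-fold. The same-numbered arrays' deviations from their diet's mean correlated at 0.05, 0.13 and -0.10, and not every array correlated best with its own number. These values give no support for pairing by number, but with 3 arrays per diet they cannot exclude it. The number of arrays and, for dim probes, the signal over background limit what can be seen. Gene lists, list scores and a slide block were not run, because the files pair no probe with a gene and name no slide. Scaling to probes detected on all arrays, treat, detection-only counts at p under 0.01, and every alternative for the 4-fold counts, the first principal component and the SD ratio were chosen after seeing the data.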

Other observations

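The 4-fold counts and the tests of brightness curve, background, batch and splits were chosen after the main counts were seen, while those of scaled detection and of the spread between arrays were set down before their values were computed.

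Of the arrays left out in turn, low-fat array 2 changed the count of large falls most. Without it, 187 probes fell by at least 4-fold in place of 99, while without low-fat array 1 or 3 the count was 100 or 91. Without high-fat array 1, 2 or 3 it was 129, 107 or 90. With array weights, lowest for low-fat arrays 3 (0.544) and 2 (0.557), it was 140. Probes that rose by at least 4-fold changed less, to 505 from 475, without low-fat array 2. On the first principal component this array lay at -52.3 against -60.6 and -63.4 for the other low-fat arrays. No biological explanation was tested, since the labels give nothing that sets this array apart.

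The first pattern weighed is that 50.0% of the tested probes were called between diets on arrays whose brightness above background differed 2.32 times, for which a single brightness curve for each array is a candidate explanation. On values with no normalization between arrays, log2 changes spread around the curve of change on signal by 4.68 times the replicate noise, and only 11.6% of their variance lay on the curve, which argues against it as the whole cause. Quantile normalization had already removed most of such a curve before the calls were made. This spread is therefore not evidence separate from the number of calls. Noise near the detection limit would spare bright probes, yet 47.3% of the brightest decile was called. In simulated arrays with the real brightness and no changed probe 1.56% of 24565 were called, 0 of 2457 in the brightest decile. Those calls had to pass a smaller unadjusted p than calls in the data, so they do not give the rate of false calls. The simulation scaled each array by a single gain, which normalization removes from bright probes. It held no batch effect on single probes, so its 0 calls there leave such effects unweighed. Diet, which the design names, and a labelling or array batch that coincides with it both stay open, because the files name no batch. The dimmest high-fat array had 1.66 times the mean signal, background included, of the brightest low-fat array. The log2 change of ILMN_2992709 was at least 4.77 under every alternative. Differences in overall brightness had been normalized before this change was computed. Its size still cannot tell diet from a batch that acts on single probes, which was not tested.

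Of the 10 splits of the 6 arrays into 3 and 3, only the real one, 1 of 10, reached 10660 calls, and 1 of 10 reached 3280 calls of at least 2-fold. The highest other split called 0 probes in limma in both counts, with 131 to 401 at an unadjusted p under 0.05 against 12135 in the real split. Every other split mixes the diets, so any difference between diets widens its within-group spread. Few calls there were fixed in advance, and these counts give no chance level. With 10 splits no share under 0.05 is possible.

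The second pattern is the 1485 probes detected on every high-fat array and no low-fat array, against 227 the other way. When their signal above background was scaled down to the brightness of each low-fat array, 48.9% lay below the low-fat detection limit on all 3 arrays, so dimmer low-fat arrays could account for their absence with no difference in transcript level. Another 43.0% (639 probes) lay above that limit on all 3 arrays and were still not detected, among them 13.9% of the whole set (206 probes) above 2 times the limit, which argues against dimness as the whole cause for these 206. The batch named in the previous pattern stays open here too.

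The third pattern is that low-fat arrays differed more from each other than high-fat arrays did, with a ratio of median within-diet SD of 1.22. The ratio was 1.52 in the dimmest decile of probes and 1.07 in the brightest, consistent with dimmer arrays being noisier near background. Low-fat array 2 as the only cause was not decided by the limits set, since the ratio without it was 1.14. The ratio did not single this array out, however. It was lower still without low-fat array 3 (1.09), high-fat array 1 (1.11) or high-fat array 2 (1.12), and higher without low-fat array 1 (1.40) or high-fat array 3 (1.52). The ratio was 1.09 to 1.52 when each array was left out, 1.03 under cyclic loess and 0.961 under median scaling over all probes, so it may not reflect variation between animals, for which no test was available.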
